A study of Mus musculus with 101 samples.

How the data were processed

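RNA sequencing of polyA RNA from mouse cortex was used, with TruSeq libraries from immunoprecipitated ribosomes (IP), cleared lysate (input) and whole tissue. The labels give the treatment, area, RNA fraction, day and sex of each of the 101 libraries, and these set the 26 groups. They do not state whether the libraries come from separate animals, nor whether PFC, VCX, IP and input libraries share animals. The p-values therefore measure the spread between libraries. The IP and input libraries of each day come from a sequencing project of their own, and the whole tissue libraries from another, so day and project cannot be separated.

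The deposited files hold FPKM values made by the authors, reads per gene scaled by gene length and by the reads summed over the listed genes. The submitters' processing notes name STAR, HTSeq and the build mm10, without versions or the gene annotation, and do not say whether reads or fragments were counted. No further scaling between libraries was found. Within a gene the values of all libraries are whole multiples of a step per gene and library, from which the reads per gene were worked back. Of 24060 entries per file, 21334 genes were above 0 in at least 1 library, reads were recovered for all of them, and 100% of values above 0 came out whole within 0.05. In simulated data all 5943 genes were recovered exactly. In 27 entries a date stood in place of a gene symbol, and 4 of these were left out because a date can stand for 2 genes. The recovered reads served for library depth, scaling factors, marker levels, the CPM limit for named genes, the limma-voom alternative and checks. The main tests were run on FPKM divided by those scaling factors, so they depend on the recovered reads only through the factors.

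The planned design assumed raw counts. Since the files hold FPKM, limma on log2 values replaced the planned count test, and camera was run on the same log2 values. FPKM were divided by scaling factors from the trimmed mean of M values, trimming 30% of M and 5% of A values, and log2-transformed after adding 0.1. A gene was tested if it reached 0.5 FPKM in at least as many libraries as the smallest group of the fit holds. The groups of a day and fraction were fitted together with sex as a covariate, except the whole tissue, which was all female. Empirical Bayes moderation used a mean trend and robust estimation, and genes with a Benjamini-Hochberg adjusted p under 0.05 are called. The 30 comparisons are LPS against PBS per day, area and fraction and in whole tissue, PFC against VCX in PBS, IP against input in PBS, and differences of LPS effects between areas, fractions and days. Reads were also simulated gene by gene from the mean and spread of the PBS libraries of a comparison, with known changes planted. For the day 1 PFC IP, 80% of 1.5-fold and 96% of 2-fold changes were recovered and 3.59% of calls were false. For whole tissue these shares were 66%, 86% and 7.37%. Whole tissue thus had the highest false share of the simulated sets. Simulated genes vary independently of each other, so the shares may be better than in the real libraries.

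Before the data were examined, 31 gene lists and 12 marker lists for other cell types were fixed, and a list was tested with at least 3 tested members. Camera used a preset correlation between genes of 0.01. It was repeated with an estimated correlation and beside fry. Adjusted p-values of lists are over the lists of a comparison. No list called by camera differed in sign between its median and the test. The median of each list called by camera kept its sign with RLE factors and without rescaling, except glycolysis, glycogen and lactate in IP against input at days 1 and 14 and the respiratory chain in the same comparison at day 1. Mean marker levels of each list were taken as log2 of scaled CPM plus 1, from the recovered reads, and compared with two-sided exact permutation tests, for which the smallest p with 4 against 4 or 3 against 4 libraries is 0.0286. Of 156 such tests 28 had an exact p under 0.05, and the lowest adjusted p was 0.159. No p can lie under 0.0286, so an adjusted p under 0.05 would have needed most of the 156 tests at that floor. The adjusted values of these tests therefore weigh little against a difference.

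Genes named in the text follow a rule fixed in advance. It took the 6 genes per direction with the largest change in each IP LPS comparison and 4 in every other comparison. These had to pass the test, have groups that do not overlap where 2 groups are compared, and a mean of at least 2 log2 CPM. Predicted, clone-named and mitochondrial genes were counted but not named. The plan named a further 12 genes for every LPS comparison whatever their result. All 12 are given in the day 1 IP comparisons, and in the others some of them, chosen after their values were seen. For members of lists, up to 4 with the largest change are printed. Results of some single genes are not reported here. Gene positions are from GENCODE vM21 on mm10.

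Settings planned in advance were RLE factors, no filter on low values, no sex covariate, leaving out each library in turn, and fitting only the groups compared. Chosen after seeing the data were limma-voom on recovered reads, no rescaling of the deposited FPKM, a pseudocount of 1, the neuron marker level as a covariate, and leaving out the 3 libraries under 10 M reads. Each result was also set against the other splits of its libraries, all 35 or 100 drawn. Sex marker genes matched the label in 101 of 101 libraries. The name of the value column matched the title in 99 libraries and not in 2 whole tissue libraries. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.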

Results

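Mice of the strain labelled C57 received an intraperitoneal injection of lipopolysaccharide (LPS, a bacterial cell wall component that triggers inflammation) at 5 mg per kg, or of phosphate-buffered saline (PBS). At 1, 2 or 14 days after the injection the cortical areas labelled PFC and VCX were homogenised. From each area, polyA RNA was sequenced from the cleared lysate, called the input, and from ribosomes precipitated through a hemagglutinin tag carried by astrocytes, called the IP. The set holds 101 libraries in 26 groups, 55 from females and 46 from males. Each combination of day, area, fraction and treatment has 4 libraries, except the day 2 PFC IP LPS and day 2 VCX input LPS groups with 3. A further 7 libraries from day 1 PFC were whole tissue, 4 labelled PBS and 3 labelled LPS, all from females.

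The reads recovered from the deposited values ran from 4.21 to 72.96 M (mega-reads) per library, with a median of 40.8 M. The IP libraries held 43.85 to 72.96 M reads at day 1, 20.68 to 50.79 M at day 2 and 12.46 to 55.1 M at day 14. The input libraries held 35.02 to 50.88 M, 13.2 to 39.64 M and 4.21 to 35.91 M at the same days, and the whole tissue libraries 35.78 to 49.49 M. Only 3 libraries, all day 14 input, lay under 10 M reads. Changes below are log2 ratios with standard errors from limma, with 4 libraries per group unless a group of 3 is named, and mean FPKM values carry the SD between libraries. List tests are by camera with a preset correlation, repeated with an estimated correlation, which is the p given alone where the call held. Positions are on the mouse build mm10.

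The comparison of IP with input in PBS mice asks which transcripts the astrocyte precipitation enriches. Kcnj10 (chromosome 1, 172341210 to 172374085), which encodes an astrocyte potassium channel, was higher in the IP at day 1 by 5.16 ± 0.13, a 35.7-fold difference, with 8 libraries per fraction. Slc1a2, the main glutamate transporter of astrocytes, was higher by 4.68 ± 0.068, Dmp1 by 4.66 ± 0.080 and Papss2 by 4.6 ± 0.061. In the other direction stood Rmrp, the RNA of a mitochondrial processing ribonuclease, at -6.93 ± 0.31, with the interneuron transcripts Sst at -5.1 ± 0.15, Pvalb at -5.01 ± 0.12 and Cck at -4.79 ± 0.071. Kcnj10 and Slc1a2 were again higher at day 2 with 5.09 ± 0.22 and 4.74 ± 0.12, followed by the transcription factor Gli3 at 4.73 ± 0.13 and the acyl-CoA synthetase Acsbg1 at 4.72 ± 0.050. Rmrp, Sst, Pvalb and Pcp4 were lower at day 2, at -6.24, -5.12, -4.91 and -4.84. At day 14 the values were 5.53 ± 0.069 for Kcnj10, 5.0 ± 0.049 for Slc1a2, 4.88 ± 0.052 for the bicarbonate cotransporter Slc4a4 and 4.87 ± 0.056 for Prex2. Rmrp, Snora74a, Gng13 and Pvalb then stood at -7.57, -5.5, -5.01 and -4.94.

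Every one of the 20 astrocyte markers was higher in the IP at day 1 (20 adjusted over the list alone; adjusted p = 0.0189 with an estimated correlation). All 16 neuron markers were lower, 16 of them adjusted over the list alone (adjusted p = 0.0407 with an estimated correlation). The same held for 16 of 16 microglia and macrophage markers, 16 adjusted over the list alone (adjusted p = 0.0231 with an estimated correlation). Meningeal fibroblast markers were higher in the IP in 9 of 10 cases, 9 adjusted over the list alone (camera adjusted p = 0.0197, lost at adjusted p = 0.368 with an estimated correlation). Of the 7 neutrophil and monocyte markers that passed the filter, which a gene can do in the IP alone, 6 were higher and 1 lower. Adjusted over the list alone it was 6 and 1, without a call by camera (adjusted p = 0.196). Genes of fatty acid oxidation and synthesis were higher in 20 of 20 cases, 20 adjusted over the list alone (adjusted p = 0.0407 with an estimated correlation). The transporters and channels of neurotransmitter, ion and water homeostasis were higher in 19 of 20 cases, 19 adjusted over the list alone (adjusted p = 0.0407 with an estimated correlation). At days 2 and 14, 20 and 20 astrocyte markers were higher and 16 and 16 neuron markers lower, called by camera but lost with an estimated correlation (adjusted p = 0.168 and 0.162 for astrocyte, 0.355 and 0.426 for neuron markers). Camera called 24, 17 and 19 lists at days 1, 2 and 14, and 7, 0 and 0 with an estimated correlation. At day 1, 12706 of 14465 tested genes differed between the fractions, 6285 higher and 6421 lower in the IP, and 12631 and 12586 differed at days 2 and 14. Without rescaling of the deposited FPKM the median of all genes moved by -0.628, -0.62 and -0.704 log2 at days 1, 2 and 14, so changes here are relative to the other genes of the same fraction.

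The LPS comparison in the PFC IP at day 1 asks how astrocyte transcripts respond within a day. Usp18, an interferon-induced deubiquitinase that removes ISG15 (chromosome 6, 121245906 to 121270917), rose 22.2-fold, from 0.622 ± 0.547 to 15.8 ± 12.2 FPKM (log2 4.47 ± 0.52, n = 4 and 4). Lcn2, which encodes the iron-sequestering protein lipocalin 2, rose from 1.38 ± 0.886 to 28.4 ± 24.9 FPKM (4.02 ± 0.69). Map3k6, a stress-activated kinase (chromosome 4, 133240818 to 133252929), rose by 3.85 ± 0.22, the interferon-induced genes Ifit1 and Iigp1 by 3.84 ± 0.47 and 3.73 ± 0.52, and the elastic fibre gene Fbln5 (chromosome 12, 101746565 to 101819055) by 3.6 ± 0.18. The named declines were in Angptl2 (chromosome 2, 33216069 to 33247717) at -1.82 ± 0.19, the lysyl oxidase gene Loxl1 at -1.76 ± 0.14, the cyclooxygenase gene Ptgs1 at -1.6 ± 0.18 and Myoc at -1.51 ± 0.17. Cd74, the invariant chain of MHC class II, changed by -1.51 ± 0.18 and the matrix glycoprotein gene Tnc by -1.33 ± 0.11.

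Gfap, the astrocyte intermediate filament gene (chromosome 11, 102887336 to 102900912), rose from 230.3 ± 14.1 to 755 ± 304 FPKM in the PFC IP (1.63 ± 0.22, adjusted p = 0.000164). The chemokine gene Cxcl10 rose 48.5-fold (5.6 ± 0.65), the protease inhibitor gene Serpina3n by 3.15 ± 0.81 and Vim, another intermediate filament gene, by 0.97 ± 0.12. Cxcl10 lay at 0 to 0.9258 FPKM in the PBS libraries, so the size of its rise leans on the added 0.1. Kcnj10 fell by 0.90 ± 0.15 and Hmgcs1, an early enzyme of cholesterol synthesis, changed by -0.62 ± 0.10. Aqp4, the water channel of astrocyte endfeet, changed by -0.30 ± 0.097 and the folate enzyme gene Aldh1l1 by 0.26 ± 0.067. The ribosomal protein gene Rpl22 rose by 0.30 ± 0.095. Slc1a2 at 0.022 ± 0.073 and the gap junction gene Gja1 at 0.037 ± 0.097 did not pass (adjusted p = 0.874 and 0.834).

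Of the interferon-stimulated genes, 28 of 28 tested members rose, 28 adjusted over the list alone (camera adjusted p = 4.35e-27, lost at adjusted p = 0.0747 with an estimated correlation). Isg15 stood at 3.54 and Oasl2 at 3.42. Of the A1 astrocyte genes, a set reported for neuroinflammatory reactive astrocytes, 11 of 11 tested members rose, 11 adjusted over the list alone (adjusted p = 0.0153 with an estimated correlation). Gbp2 stood at 2.91 and Fkbp5 at 2.92. Of the A2 genes, reported for astrocytes after ischaemia, 5 of 8 tested members rose and 0 fell, 5 and 1 adjusted over the list alone, Cd109 at 2.53 and Cd14 at 2.07 among them (camera adjusted p = 0.000943, lost at adjusted p = 0.0502 with an estimated correlation). The pan-reactive genes had 12 of 13 members up, 13 adjusted over the list alone (camera adjusted p = 1.91e-13, lost at adjusted p = 0.0502 with an estimated correlation). Timp1 stood at 3.82. For MHC class I and antigen processing, 12 of 14 tested members rose, 12 adjusted over the list alone (camera adjusted p = 1.41e-10, lost at adjusted p = 0.127 with an estimated correlation). Psmb8 and Psmb9, immunoproteasome genes, stood at 2.74 and 2.58, and H2-T23 at 2.39. Complement gave 10 of 13 members up, 10 adjusted over the list alone (adjusted p = 0.00307 with an estimated correlation). Cfb stood at 3.45, C3 at 3.26 and C1ra at 2.67. In the STAT3 and acute phase list, 14 of 16 tested members rose, 14 adjusted over the list alone (adjusted p = 0.00547 with an estimated correlation). The serum amyloid gene Saa3 stood at 7.61 and Lrg1 at 2.53. Saa3 lay at 0 to 0.1728 FPKM in the PBS libraries, so the size of its rise leans on the added 0.1.

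Of the cytokine and chemokine genes, 6 of 13 tested members rose, 7 adjusted over the list alone (camera adjusted p = 0.000626, lost at adjusted p = 0.11 with an estimated correlation). Ccl12 stood at 3.7, Ccl2 at 3.32 and Il1b at 3.06. For NF-kB targets and regulators, 7 of 17 tested members rose, 1 fell and 9 did not pass, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.000758, lost at adjusted p = 0.141 with an estimated correlation). Tlr2 stood at 2.64 and Icam1 at 1.95. Glucocorticoid-responsive genes showed 7 of 16 members up, 7 adjusted over the list alone (camera adjusted p = 0.000182, lost at adjusted p = 0.144 with an estimated correlation). The lipid droplet gene Plin4 stood at 3.53 and the steroid receptor co-chaperone gene Fkbp5 at 2.92. Among heat shock genes 8 of 12 tested members rose, 8 adjusted over the list alone (adjusted p = 0.00633 with an estimated correlation). Hspb1 stood at 1.79 and Hspa1b at 0.90. Cholesterol synthesis went the other way: 16 of 23 tested members fell and 0 rose, 19 and 1 adjusted over the list alone, Mvd at -1.06 and Dhcr7 at -0.74 (camera adjusted p = 8.99e-10, lost at adjusted p = 0.0521 with an estimated correlation). Cytosolic ribosomal protein genes had 20 of 78 up and 1 down, 20 and 1 adjusted over the list alone (camera adjusted p = 5.62e-08, lost at adjusted p = 0.141 with an estimated correlation). For the nuclear genes of the respiratory chain, 17 of 88 tested members rose, 17 adjusted over the list alone (camera adjusted p = 1.34e-05, lost at adjusted p = 0.252 with an estimated correlation). Metallothionein and antioxidant genes had 5 of 16 up and 0 down, 9 and 1 adjusted over the list alone (camera adjusted p = 0.00967, lost at adjusted p = 0.141 with an estimated correlation). Gsr stood at 0.70. In the cell cycle list 2 of 9 tested members rose, 3 adjusted over the list alone, the cell cycle inhibitor gene Cdkn1a at 1.85 and the replication clamp gene Pcna at 0.22 (camera adjusted p = 0.0232, lost at adjusted p = 0.202 with an estimated correlation).

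Markers of other cell types moved in the same PFC IP libraries. Of the microglia and macrophage markers, 10 of 15 tested members rose, 2 fell and 3 did not pass, with 10 and 2 adjusted over the list alone (camera adjusted p = 2.52e-06, lost at adjusted p = 0.0521 with an estimated correlation). Itgam stood at 2.31, C1qb at 1.88 and Tyrobp at 1.69. The mean log2 level of the microglia and macrophage markers was 2.711 ± 0.104 in LPS and 2.078 ± 0.128 in PBS libraries (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.159). For neutrophil and monocyte markers 12 of 15 tested members rose, 12 adjusted over the list alone (camera adjusted p = 3.92e-10, lost at adjusted p = 0.0747 with an estimated correlation). Plac8 stood at 3.21, Chil3 at 3.07 and S100a8 at 2.91. Pericyte and smooth muscle markers went down in 4 of 5 cases, 5 adjusted over the list alone (camera adjusted p = 0.0038, lost at adjusted p = 0.0502 with an estimated correlation). Vtn stood at -1.01 and Pdgfrb at -0.34. Across all genes, limma called 2800 of 13163, 1417 up and 1383 down, of which 368 rose and 55 fell at least 2-fold.

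In the VCX IP at day 1 the same question was asked of the other area. Lcn2 rose by 5.6 ± 0.69, with Iigp1 at 4.07 ± 0.52, the calprotectin gene S100a9 at 3.89 ± 0.43, Usp18 at 3.7 ± 0.52, Ifit1 at 3.7 ± 0.47 and Map3k6 at 3.54 ± 0.22. Angptl2 stood at -1.67 ± 0.19, Tnc at -1.59 ± 0.11, Loxl1 at -1.46 ± 0.14, Ptgs1 at -1.42 ± 0.18, the vascular peptide gene Apln at -1.33 ± 0.13 and Fabp7, a fatty acid binding protein gene of astrocytes and progenitors, at -1.3 ± 0.22. Gfap rose by 1.46 ± 0.22, Vim by 0.98 ± 0.12, Serpina3n by 3.36 ± 0.81, Cxcl10 by 5.7 ± 0.65 and Aldh1l1 by 0.25 ± 0.067. Kcnj10 was at -0.89 ± 0.15, Hmgcs1 at -0.83 ± 0.10 and Aqp4 at -0.50 ± 0.097. Rpl22 at 0.21 ± 0.095 did not pass (adjusted p = 0.135), nor did Slc1a2 at 0.045 ± 0.073 or Gja1 at -0.016 ± 0.097 (adjusted p = 0.701 and 0.927).

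By group, 28 of 28 interferon-stimulated genes rose in the VCX IP, 28 adjusted over the list alone, Isg15 at 3.83 and Irf7 at 3.28 (camera adjusted p = 2.36e-23, lost at adjusted p = 0.112 with an estimated correlation). For A1 genes 11 of 11 tested members rose, 11 adjusted over the list alone (adjusted p = 0.0306 with an estimated correlation). For A2 genes 4 of 8 tested members rose, 5 adjusted over the list alone (adjusted p = 0.0361 with an estimated correlation). Complement had 12 of 13 up, 12 adjusted over the list alone, Cfb at 3.88 and C3 at 3.17 (adjusted p = 0.00247 with an estimated correlation). In cholesterol synthesis 19 of 23 tested members fell, 19 adjusted over the list alone, Mvd at -1.26, Dhcr7 at -0.98 and Fdps at -0.89 (adjusted p = 0.031 with an estimated correlation). The homeostasis list had 1 up and 7 down of 20, 1 and 8 adjusted over the list alone (camera adjusted p = 0.0463, lost at adjusted p = 0.515 with an estimated correlation). The glycine transporter gene Slc6a9 stood at -0.98, the glutamine transporter gene Slc38a3 at -0.77 and the connexin gene Gjb6 at 0.87. Neutrophil and monocyte markers moved beside them: 14 of 15 tested members rose, 14 adjusted over the list alone, Chil3 at 4.19 and Mmp8 at 3.63 (adjusted p = 0.0426 with an estimated correlation). So did microglia and macrophage markers, 11 of 15 up and 2 down, 11 and 2 adjusted over the list alone (camera adjusted p = 2.74e-06, lost at adjusted p = 0.0571 with an estimated correlation). Endothelial markers rose in 6 of 11 cases, 6 adjusted over the list alone (camera adjusted p = 0.000788, lost at adjusted p = 0.198 with an estimated correlation). Ly6a stood at 1.98 and Pecam1 at 1.55.

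Limma called 2861 of 13163 genes in the VCX IP at day 1, 1564 up and 1297 down, 390 and 37 of them by at least 2-fold, and 1832 when these groups were fitted alone. Of the genes up in PFC and VCX, 1093 were shared where 168 were expected, and of the genes down 845 where 136 were expected. Changes correlated at Pearson r = 0.841 across genes, which are not independent replicates, and the areas share no libraries but may share animals.

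**Figure D1:**
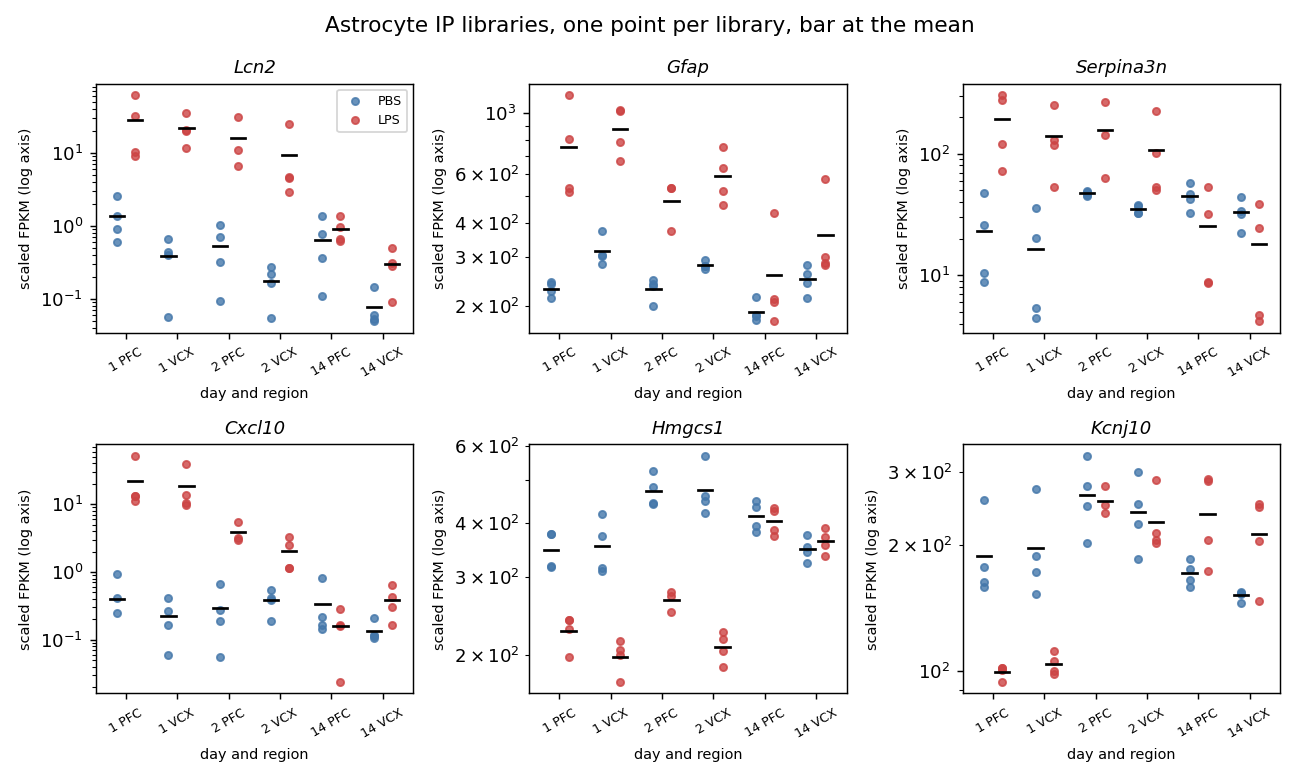
Scaled FPKM of Lcn2, Gfap, Serpina3n, Cxcl10, Hmgcs1 and Kcnj10 in every IP library, on a log axis, by day and area, with 1 point per library, PBS in blue, LPS in red and a bar at each group mean. In the PFC at day 1 mean Gfap was 754.9 FPKM in LPS and 230.3 FPKM in PBS libraries.

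At day 2 the IP comparison asks what the astrocyte fraction holds as the response proceeds. In the PFC, with 3 LPS and 4 PBS libraries, the interferon-induced gene Oasl2 (chromosome 5, 114896936 to 114912234) rose 16.1-fold (4.01 ± 0.28) and the lysozyme gene Lyz2 (chromosome 10, 117277331 to 117282321) rose 14.6-fold (3.87 ± 0.43). The leukocyte integrin gene Itgb2 was at 3.32 ± 0.29, the phagocyte oxidase gene Cybb at 3.26 ± 0.31, and the antiviral genes Bst2 and Ifitm3 at 3.15 ± 0.24 and 3.05 ± 0.12. All 6 named declines were enzymes of sterol synthesis or its acetate supply. Fdps (chromosome 3, 89093588 to 89101959) changed by -0.98 ± 0.14, Mvd by -0.98 ± 0.15, Acss2 by -0.86 ± 0.093, Lss by -0.84 ± 0.090, Mvk by -0.82 ± 0.11 and Hmgcs1 by -0.82 ± 0.096. Lcn2 rose by 4.75 ± 0.79, Gfap by 1.07 ± 0.15, Cxcl10 by 3.5 ± 0.52, Vim by 0.70 ± 0.14 and Serpina3n by 1.62 ± 0.43 (adjusted p = 0.0399). Kcnj10 was at -0.063 ± 0.17, Aldh1l1 at -0.10 ± 0.054, Gja1 at 0.18 ± 0.080 and Rpl22 at -0.072 ± 0.072, none of which passed (adjusted p = 0.869, 0.294, 0.196 and 0.613).

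In the VCX IP at day 2, Lyz2 rose by 4.3 ± 0.40, S100a9 by 3.85 ± 0.49, Itgb2 by 3.51 ± 0.27, Oasl2 by 3.48 ± 0.26, Bst2 by 3.43 ± 0.22 and Psmb8 by 3.38 ± 0.21. Sterol enzymes again made up the named declines, with Mvd at -1.18 ± 0.14, Hmgcs1 at -1.18 ± 0.089, Idi1 at -1.17 ± 0.12, Fdps at -1.14 ± 0.13, Mvk at -1.03 ± 0.096 and Lss at -0.97 ± 0.083. Gfap rose by 1.06 ± 0.14, Lcn2 by 4.6 ± 0.72 and Cxcl10 by 2.05 ± 0.48, while Serpina3n at 1.32 ± 0.39 and Vim at 0.44 ± 0.13 did not pass (adjusted p = 0.0709 and 0.0624).

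For cholesterol synthesis at day 2, 19 of 23 tested members fell and 1 rose, 19 and 1 adjusted over the list alone in the PFC IP (camera adjusted p = 4.69e-19, lost at adjusted p = 0.0712 with an estimated correlation). In the VCX IP 19 of 23 tested members fell, 22 adjusted over the list alone (adjusted p = 0.0233 with an estimated correlation). MHC class I and antigen processing showed 12 of 12 and 12 of 12 up, the same numbers adjusted over the list alone, with H2-D1 at 2.33 and 2.61 (adjusted p = 0.0042 and 0.00224 with an estimated correlation). In the interferon list, 27 of 28 tested members rose, 28 adjusted over the list alone in PFC and 26 of 28 tested members rose, 28 adjusted over the list alone in VCX (adjusted p = 0.0147 and 0.017 with an estimated correlation). Complement rose in 11 and 10 of 13 cases, 12 and 12 adjusted over the list alone, C3 at 3.14 and 3.46 (adjusted p = 0.0117 and 0.00849 with an estimated correlation). A1 genes were up in 9 and 8 of 11, 10 and 9 adjusted over the list alone (adjusted p = 0.0117 and 0.00858 with an estimated correlation). In the list of cholesterol export and lipoproteins, Apod was at 1.8 and 1.75 and the sterol transporter gene Abca1 at 0.48 and 0.71. There 3 of 14 tested members rose, 5 adjusted over the list alone in PFC (camera adjusted p = 0.00313, lost at adjusted p = 0.07 with an estimated correlation) and 4 of 14 tested members rose, 6 adjusted over the list alone in VCX (camera adjusted p = 0.00517, lost at adjusted p = 0.0799 with an estimated correlation).

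Myeloid markers moved with these groups. Microglia and macrophage markers rose in 10 of 16 cases in the PFC IP and 14 of 16 in the VCX IP, 14 and 14 adjusted over the list alone, with Ctss at 2.65 and 2.85 (adjusted p = 0.028 and 0.0135 with an estimated correlation). The mean log2 level of the microglia and macrophage markers was higher in LPS libraries by 1.119 in PFC and 1.245 in VCX (exact permutation p = 0.0286 and adjusted p = 0.159 for each, 3 or 4 against 4). For neutrophil and monocyte markers, 10 of 13 tested members rose, 12 adjusted over the list alone in PFC (camera adjusted p = 6.2e-13, lost at adjusted p = 0.0571 with an estimated correlation). In VCX 12 of 13 tested members rose, 13 adjusted over the list alone (adjusted p = 0.0228 with an estimated correlation). Endothelial markers rose in 6 of 13 and 4 of 13 cases, 6 and 9 adjusted over the list alone, Pecam1 at 1.56 and 1.5 (camera adjusted p = 1.19e-06 and 1.12e-07, with an estimated correlation 0.0886 and 0.0665). Limma called 1069 of 13452 genes in PFC, 696 up and 373 down. In VCX it called 975, 580 up and 395 down, and the areas shared 461 genes up (30 expected) and 181 down (11 expected). With the groups fitted alone the counts were 699 and 441, without LPS replicate 1 the PFC count was 640, and the VCX count was 578 without PBS replicate 3 and 631 without LPS replicate 1.

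At day 14 the question is whether astrocyte changes persist. No gene passed limma in any of the 4 comparisons, and limma-voom also called 0 in each. At an unadjusted p under 0.05 there were 173 of 12958 genes in the PFC IP, 270 of 12958 in the VCX IP, 599 of 14398 in the PFC input and 660 of 14398 in the VCX input. Chance gives about 1 in 20 genes, and each count lies under that share, most of all in the IP. These counts are no sign of remaining changes, nor of their absence. Gfap was at 0.34 ± 0.24 in the PFC IP and 0.47 ± 0.24 in the VCX IP, Kcnj10 at 0.44 ± 0.17 and 0.46 ± 0.17, and Lcn2 at 0.71 ± 0.51 and 1.08 ± 0.51. Serpina3n was at -1.2 ± 0.54 and -1.44 ± 0.54, and each of these values had an adjusted p of 1. Gfap stood at 435 FPKM in PFC LPS replicate 1 against 175.3 to 212.1 in the other LPS libraries, and at 574.7 in VCX LPS replicate 2 against 279.7 to 300. In females Serpina3n was at 8.736 and 8.882 FPKM in LPS and 46.55 and 42.44 in PBS libraries of the PFC IP, and at 4.195 and 4.754 against 31.65 and 34.11 in the VCX IP. In males it was at 53 and 31.88 in LPS and 57.18 and 32.61 in PBS libraries of PFC, and 38.51 and 24.32 against 22.14 and 43.64 in VCX. Whether the effect on Serpina3n differs between sexes was not tested. In the VCX IP the camera test called 14 of 40 lists and in the PFC IP 1 of 40, with 0 called under an estimated correlation in either. Among them, pan-reactive genes had a median of 0.44 in VCX and 0 of 10 members passing, 0 adjusted over the list alone (camera adjusted p = 7.2e-05, lost at adjusted p = 0.206 with an estimated correlation). Neutrophil and monocyte markers had a median of 0.77 in PFC and 0.72 in VCX, with 0 and 2 members up adjusted over the list alone (camera adjusted p = 5.94e-05 and 6.56e-05, with an estimated correlation 0.908 and 0.206). Reads were simulated from the mean and spread of day 14 PBS libraries. The same fit then recovered 96% of planted 2-fold changes for the PFC IP and 94% for the VCX input. Simulated genes vary independently of each other, so recovery in the real libraries may be lower. The test of the difference between day 1 and day 14 called 3453 genes in the IP, 1670 with a difference, day 1 minus day 14, above 0 and 1783 below 0.

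**Figure D2:**
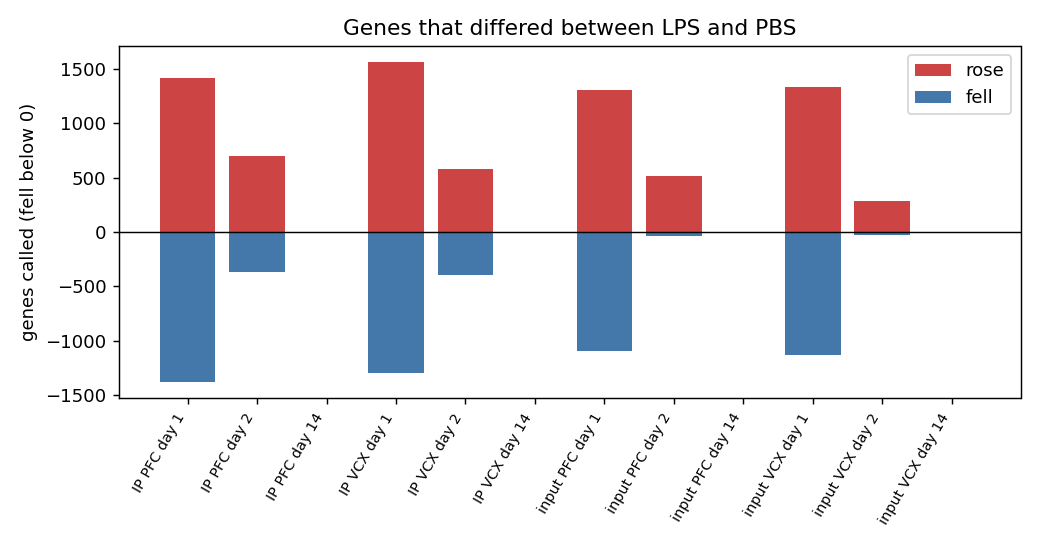
Number of genes called by limma for LPS against PBS in each IP and input comparison, with genes that rose above 0 and genes that fell below 0. The bars of the day 1 PFC IP stand at 1417 and 1383 genes, and those of day 14 are at 0.

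In the input, LPS against PBS asks how the whole lysate of the cortex responds. At day 1 Saa3, an acute phase gene (chromosome 7, 46711998 to 46715700), rose by 9.31 ± 0.50 in PFC and 9.49 ± 0.50 in VCX. In PBS libraries Saa3 lay at 0 to 0.2396 FPKM in PFC and 0 to 0.2062 FPKM in VCX, so the size of its rise leans on the added 0.1. In LPS libraries it lay at 61.51 to 261.8 and 66.17 to 179.6 FPKM. The chemokine gene Ccl12 rose by 6.71 ± 0.64 and 6.16 ± 0.64, Lcn2 by 5.08 ± 0.63 and 6.15 ± 0.63, and the macrophage scavenger receptor gene Msr1 by 4.83 ± 0.30 and 4.48 ± 0.30. The named declines included the microglial genes P2ry12 (chromosome 3, 59216272 to 59262871) at -2.0 ± 0.13 and -2.1 ± 0.13, Siglech at -1.55 ± 0.17 and -1.31 ± 0.17, and Gpr34 at -1.48 ± 0.18 and -1.68 ± 0.18. The organic anion transporter gene Slc22a8 was at -1.4 ± 0.20 in PFC and Apln at -1.31 ± 0.14 in VCX. Gfap rose by 1.58 ± 0.22 and 1.43 ± 0.22, Cxcl10 by 4.77 ± 0.43 and 4.29 ± 0.43, and Hmgcs1 changed by -0.76 ± 0.064 and -0.75 ± 0.064. Serpina3n at 1.25 ± 0.86 and 1.68 ± 0.86 did not pass (adjusted p = 0.363 and 0.223). Kcnj10 passed in PFC at -1.02 ± 0.18 (adjusted p = 0.00104) and was at -0.46 ± 0.18 in VCX (adjusted p = 0.0924).

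For cytokines and chemokines in the day 1 PFC input, 13 of 18 tested members rose, 3 fell and 2 did not pass, with 13 and 3 adjusted over the list alone (adjusted p = 0.012 with an estimated correlation). Ccl2 stood at 5.03 and Tnf at 4.2. NF-kB targets and regulators had 12 of 16 up, 14 adjusted over the list alone, Tlr2 at 4.19 and Icam1 at 2.35 (adjusted p = 0.00422 with an estimated correlation). In the list of the unfolded protein and integrated stress response, 9 of 14 tested members rose, 1 fell and 4 did not pass, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.00047, lost at adjusted p = 0.0838 with an estimated correlation). Sdf2l1 stood at 1.38 and the chaperone gene Hspa5 at 0.72. Meningeal fibroblast markers had 6 of 10 down and 0 up, 7 and 1 adjusted over the list alone (camera adjusted p = 0.000836, lost at adjusted p = 0.226 with an estimated correlation). Slc22a6 stood at -1.45 and Lum at -1.16. Microglia and macrophage markers split, 11 of 16 up and 3 down, 12 and 3 adjusted over the list alone (adjusted p = 0.0169 with an estimated correlation). Endothelial markers showed 8 of 14 up and 1 down, 8 and 1 adjusted over the list alone, Ly6c1 at 1.29 and Vwf at 1.02 (adjusted p = 0.0452 with an estimated correlation). For neuron markers 3 of 16 tested members fell, 4 adjusted over the list alone (camera adjusted p = 0.00428, lost at adjusted p = 0.304 with an estimated correlation). Tubb3 stood at -0.46. In the VCX input, oligodendrocyte markers had 7 of 12 down and 0 up, 7 and 2 adjusted over the list alone, Opalin at -0.97 (camera adjusted p = 0.00982, lost at adjusted p = 0.386 with an estimated correlation). Limma called 2409 of 14676 genes in PFC, 1310 up and 1099 down, and 2470 in VCX, 1334 up and 1136 down. Without rescaling of the deposited FPKM the PFC split was 1543 up and 815 down.

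At day 2 Saa3 in the input rose, at 8.81 ± 0.56 in PFC and 7.49 ± 0.60 in VCX, the latter with 3 LPS libraries. Lyz2 rose by 2.6 ± 0.18 and 2.24 ± 0.20, the interferon regulator gene Irf7 by 2.2 ± 0.16 and 2.15 ± 0.18, and the macrophage gene Emr1 by 2.2 ± 0.17 and 1.79 ± 0.18. Gfap rose by 1.1 ± 0.16 and 0.96 ± 0.17, Lcn2 by 4.04 ± 0.58 and 4.41 ± 0.63 and Vim by 0.93 ± 0.11 and 0.77 ± 0.12, while Cxcl10 passed in PFC at 2.12 ± 0.42 (adjusted p = 0.00737) and was at 1.26 ± 0.45 in VCX (adjusted p = 0.265). The troponin gene Tnnc1 was at -1.09 ± 0.15 and -1.03 ± 0.16. Robo3, Idi1 and Myl4 changed by -0.71 ± 0.19, -0.66 ± 0.14 and -0.64 ± 0.096 in PFC, and Slc22a8, Msmo1 and Steap3 by -0.63 ± 0.14, -0.60 ± 0.13 and -0.55 ± 0.13 in VCX. Cell cycle genes rose in the PFC input in 7 of 14 cases, 8 adjusted over the list alone (adjusted p = 0.0072 with an estimated correlation). Top2a stood at 1.77, Cdk1 at 1.58 and Ccnb1 at 1.6. In VCX 2 of 14 tested members rose, 6 adjusted over the list alone (adjusted p = 0.0248 with an estimated correlation). Microglia and macrophage markers were up in 14 of 16 and 12 of 16 cases, 14 and 13 adjusted over the list alone, Aif1 at 1.48 and 1.28 (adjusted p = 0.0072 and 0.0248 with an estimated correlation). Cholesterol synthesis had 12 and 9 of 24 members down, 18 and 17 adjusted over the list alone (adjusted p = 0.0111 and 0.0248 with an estimated correlation). Limma called 557 of 14661 genes in PFC, 516 up and 41 down, and 313 in VCX, 286 up and 27 down. The VCX count was 115 with its groups fitted alone and 158 without LPS replicate 2.

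The whole tissue libraries of day 1 PFC address the same LPS question without fractionation, with 4 libraries labelled PBS and 3 labelled LPS. Gfap was at 1.61 ± 0.46, Lcn2 at 5.0 ± 1.56, Cxcl10 at 4.77 ± 1.5 and Serpina3n at 2.69 ± 0.73, none of which passed (adjusted p = 0.194, 0.212, 0.208 and 0.188). Lcn2 ran from 0.224 to 22.8 FPKM in the libraries labelled PBS and from 40.4 to 52 FPKM in those labelled LPS. Limma called 1 of 14788 genes, Mir6997, chosen after its values were seen, at 1.19 FPKM in LPS and listed at 0 in PBS libraries, while 2594 genes had an unadjusted p under 0.05 and limma-voom called 250. Interferon-stimulated genes had a median of 2.17 with 0 of 29 passing over all genes and 29 rising adjusted over the list alone (camera adjusted p = 2.16e-19, lost at adjusted p = 0.316 with an estimated correlation). For MHC class I and antigen processing the median was 1.4, with 0 of 14 passing and 14 rising adjusted over the list alone (camera adjusted p = 6.54e-12, lost at adjusted p = 0.316 with an estimated correlation). Mean marker levels were higher in LPS libraries by 0.468 for microglia and macrophages, 0.455 for endothelium, 0.542 for neutrophils and monocytes and 0.072 for lymphocytes (exact permutation p = 0.0857, 0.114, 0.0571 and 0.0286, adjusted p = 0.304, 0.35, 0.235 and 0.159). The library labelled PBS replicate 3 lay at 0.898 on a scale from the other PBS libraries at 0 to the LPS libraries at 1. Without it, limma called 1432 of 14717 genes, 1048 up and 384 down.

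**Figure D3:**
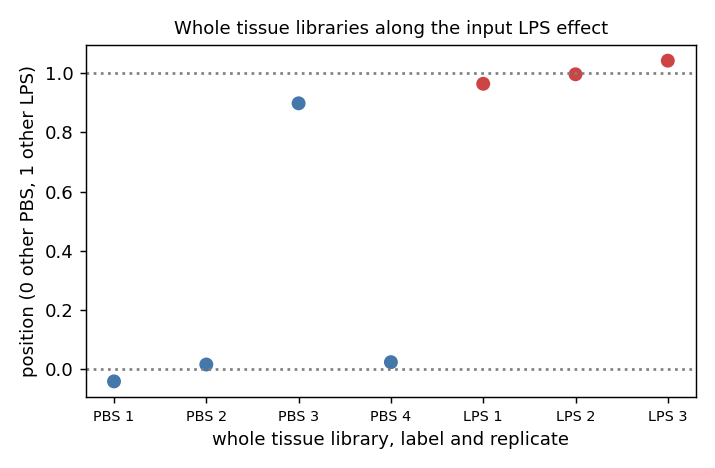
Position of each of the 7 whole tissue libraries between the other libraries labelled PBS (0) and the other libraries labelled LPS (1), over 335 genes. PBS replicate 3 stands at 0.898 and the other PBS libraries between -0.041 and 0.024.

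PFC against VCX in PBS mice asks which transcripts distinguish the areas without inflammation. In the IP, Cyp27a1, a sterol hydroxylase gene (chromosome 1, 74713574 to 74737892), was higher in PFC by 2.07 ± 0.16, 2.45 ± 0.14 and 2.43 ± 0.20 at days 1, 2 and 14. Nr2f1, a transcription factor gene of caudal cortex identity (chromosome 13, 78188973 to 78199757), stood at -2.21, -2.11 and -2.24. Aldh1a1, a retinoic acid synthesis gene, stood at -1.99 ± 0.093, the secreted phosphoprotein gene Spp1 at -1.83 ± 0.18 and Hdc, the histamine-synthesising decarboxylase, at -1.74 ± 0.11 at day 1. Also higher in PFC at day 1 were the phospholipase gene Pla2g5 at 1.89 ± 0.17, the sulfotransferase gene Chst7 at 1.86 ± 0.16 and Greb1 at 1.81 ± 0.13. Zic1 was higher at days 2 and 14 by 2.51 ± 0.30 and 2.07 ± 0.29, and at day 2 Efna5, an axon guidance ligand, and the collagen gene Col1a2 by 1.71 ± 0.15 and 1.67 ± 0.16. Nr4a2 was at -2.25 ± 0.34 at day 14.

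In the input, the netrin gene Ntn5 (chromosome 7, 45684022 to 45694556) was lower in PFC than in VCX, at -2.66 ± 0.19, -2.75 ± 0.16 and -2.59 ± 0.22, and Nr4a2 followed at -2.14, -2.02 and -2.44. Higher in PFC were the retinoid receptor gene Rxrg at 2.0, 2.04 and 2.09, the nicotinic receptor gene Chrna5 at 1.79 and 1.98 at days 1 and 2, and Cep112 at 2.02 and L3mbtl4 at 1.87 at day 1. Cortical layer 4 markers were lower in PFC at every day: 9 of 9 at day 1, 9 adjusted over the list alone (adjusted p = 0.0133 with an estimated correlation). Scnn1a stood at -1.84, Rorb at -1.32 and Whrn at -1.26. At days 2 and 14 it was again 9 of 9, 9 adjusted over the list alone (adjusted p = 0.00948 and 0.0031 with an estimated correlation). Genes of serotonin, dopamine and noradrenaline handling were higher in PFC in 3 of 7 cases at day 1, 3 adjusted over the list alone (adjusted p = 0.047 with an estimated correlation). Htr2c and Htr2a, serotonin receptor genes, stood at 1.15 and 0.92, and the monoamine oxidase gene Maob at 0.59. Immediate early genes were lower in 9 of 15 cases at day 2, 15 adjusted over the list alone (camera adjusted p = 6.44e-09, lost at adjusted p = 0.266 with an estimated correlation).

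In the IP, layer 4 markers were lower in PFC in 6 of 8 cases at day 2, 7 adjusted over the list alone (camera adjusted p = 1.57e-05, lost at adjusted p = 0.202 with an estimated correlation). Interferon-stimulated genes were higher at day 14 in 7 of 21 cases, 7 adjusted over the list alone (camera adjusted p = 3.36e-06, lost at adjusted p = 0.215 with an estimated correlation), beside neutrophil and monocyte markers, of which 3 of 6 were higher, 6 adjusted over the list alone (camera adjusted p = 7.45e-06, lost at adjusted p = 0.178 with an estimated correlation). Limma called 1027, 1033 and 624 genes between the areas in the IP at days 1, 2 and 14, and 1987, 2392 and 1167 in the input. At day 1 the IP count was 680 without PFC PBS replicate 1 and 2509 without VCX PBS replicate 4, and at day 2 it was 667 without PFC PBS replicate 4. With the neuron marker level as a covariate the day 14 IP count was 1327, and with the areas fitted alone the day 2 input count was 1434. For the day 1 IP, day 14 IP and day 14 input, 2 of the 35 splits of the 8 libraries called as many genes as the real one.

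Whether LPS acted differently in PFC and VCX was tested in the IP as the difference of the LPS effects. The fit treated the libraries of both areas as independent. If the areas share animals, which the labels do not state, it ignores that pairing and can miss differences. Limma called 0 genes at days 1, 2 and 14, limma-voom also 0 at each, and 432, 506 and 74 genes had an unadjusted p under 0.05. Chance gives about 1 in 20 of the tested genes, and each of these counts lies under that share. The differences, PFC minus VCX, were 0.18 ± 0.32 for Gfap, -1.58 ± 0.97 for Lcn2 and 0.22 ± 0.14 for Hmgcs1 at day 1, and 1.45 ± 0.71 for Cxcl10 at day 2 (adjusted p = 0.999 for each). Camera called 7, 7 and 11 of 40 lists at the respective days and 0 with an estimated correlation. The neutrophil and monocyte markers had a median difference of -0.91 at day 1 with 0 of 15 passing, 0 adjusted over the list alone (camera adjusted p = 1.81e-06, lost at adjusted p = 0.477 with an estimated correlation).

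The difference of the LPS effect between IP and input asks which changes differ between the fractions. At day 1 Map3k6 responded more in the IP by 3.05 ± 0.20, Fbln5 by 2.59 ± 0.17, the matrix gene Tgfbi by 2.16 ± 0.20 and Ifit1 by 1.91 ± 0.39. Ctla2a stood at -1.83 ± 0.18, Ptgs1 at -1.59 ± 0.15, the lysosomal protease gene Ctsc at -1.58 ± 0.14 and Adamts9 at -1.56 ± 0.12. Of the A1 genes, 8 of 11 had a difference, IP minus input, above 0, 11 adjusted over the list alone (adjusted p = 0.0207 with an estimated correlation). NF-kB targets and regulators had 6 of 18 with a difference below 0, 6 adjusted over the list alone (camera adjusted p = 0.000228, lost at adjusted p = 0.0836 with an estimated correlation). Among cytokine and chemokine genes 9 of 19 had a difference below 0 and 1 above 0, 9 and 3 adjusted over the list alone (camera adjusted p = 0.00174, lost at adjusted p = 0.178 with an estimated correlation). At day 2 H2-T23, a non-classical MHC class I gene (chromosome 17, 36029773 to 36032855), was at 2.85 ± 0.25, Oasl2 at 2.3 ± 0.25, Itgb2 at 2.01 ± 0.23 and Psmb8 at 1.77 ± 0.24, with Lacc1, Cav1, Apobec3 and Cebpa at -1.06, -0.89, -0.89 and -0.87. In cholesterol synthesis 11 of 24 genes had a difference below 0 and 0 above 0, 18 and 1 adjusted over the list alone, Hmgcs1 at -0.44 ± 0.098 (camera adjusted p = 1.19e-15, lost at adjusted p = 0.0973 with an estimated correlation). Microglia and macrophage markers had a difference above 0 in 9 of 16 cases at day 1 and 9 of 16 at day 2, 10 and 9 adjusted over the list alone, and 1 marker was below 0 at each day (camera adjusted p = 1.76e-05 and 4.6e-10, with an estimated correlation 0.0836 and 0.116). The counts were 2316 genes at day 1 and 550 at day 2, with 0 at day 14 by limma and limma-voom. At day 14, 570 of 14746 genes had an unadjusted p under 0.05, fewer than the 1 in 20 that chance gives. Without rescaling of the deposited FPKM, the day 1 split of 1237 above 0 and 1079 below 0 became 968 and 1454, and the day 2 split of 356 and 194 became 269 and 370.

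The difference of the IP LPS effect between days asks which changes are early. The IP libraries of each day come from a separate sequencing project, so a difference between days cannot be told apart from one between projects. Relative to day 2, Plin4 (chromosome 17, 56100591 to 56109803) was higher at day 1 by 2.44 ± 0.28, Fkbp5 by 2.26 ± 0.42, the protease inhibitor gene A2m by 1.86 ± 0.26, Rtp1 by 1.72 ± 0.25 and Cxcl10 by 2.88 ± 0.56. Lyz2 was lower at -1.82 ± 0.33, with Nptx2 at -1.59 ± 0.42, the macrophage pore gene Mpeg1 at -1.55 ± 0.23, Angptl2 at -1.54 ± 0.27 and Kcnj10 at -0.84 ± 0.17. Heat shock genes had a difference, day 1 minus day 2, above 0 in 4 of 12 cases, 5 adjusted over the list alone (adjusted p = 0.0383 with an estimated correlation), and microglia and macrophage markers a difference below 0 in 9 of 16, 10 adjusted over the list alone (camera adjusted p = 1.61e-05, lost at adjusted p = 0.26 with an estimated correlation). The test called 2614 genes, 1198 above 0 and 1416 below 0, and without rescaling 1526 and 1190. Relative to day 14, Serpina3n was higher by 4.56 ± 0.63, Ifit1 by 3.6 ± 0.45, Plin4 by 3.51 ± 0.27, Oasl2 by 3.1 ± 0.41 and Gfap by 1.13 ± 0.22. Angptl2, Loxl1, Ptgs1, Tnc and Kcnj10 were at -1.91, -1.66, -1.55, -1.52 and -1.36. The A1 genes differed in 11 of 11 cases, 11 adjusted over the list alone (adjusted p = 0.00107 with an estimated correlation). Neutrophil and monocyte markers were above 0 in 12 of 15 cases, 12 adjusted over the list alone (adjusted p = 0.0474 with an estimated correlation). Microglia and macrophage markers had 11 of 16 above and 2 below 0, 11 and 2 adjusted over the list alone (camera adjusted p = 7.55e-05, lost at adjusted p = 0.22 with an estimated correlation). Endothelial markers had 5 of 13 above 0, 5 adjusted over the list alone (camera adjusted p = 0.0127, lost at adjusted p = 0.426 with an estimated correlation).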

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

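The tests of the whole tissue library, of the myeloid markers and of day 14 were chosen after those results were seen, while the other splits of the libraries were planned.

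In day 1 PFC whole tissue, the library labelled PBS replicate 3 stood at 0.898 between the other PBS libraries (0) and the LPS libraries (1), over 335 genes. The other PBS libraries lay at -0.041, 0.016 and 0.024. Fewer reads do not account for it, since its depth was 0.814 of the median of the others, and neither does a swap with an LPS library analysed here, as the lowest LPS position was 0.964. A mixture of PBS and LPS RNA cannot be told apart from a full response, because the spread of the shares was 1.118 times that of the widest LPS library. These shares were taken over the 242 genes that rose in the input and had a mean of at least 1 FPKM in whole tissue. A wrong label or a file attached to another sample is in line with the position of 0.898, and the value columns of PBS replicates 3 and 4 carry the numbers 65 and 67 where their titles carry 67 and 68, while an exposure of that animal to another inflammatory stimulus was not tested.

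Myeloid transcripts rose in the astrocyte IP after LPS, with Lyz2 at 70.3 ± 32 FPKM in the day 2 PFC LPS libraries against 4.40 ± 1.92 in PBS (SD, n = 3 and 4) although the tag is carried by astrocytes. In PBS mice microglia and macrophage markers were lower in the IP than in the input at day 1, 16 of 16. Neutrophil and monocyte markers were tested only where they passed the filter, which a gene can do in the IP alone. Of these, 6 of 7 were higher in the IP at day 1 with a median log2 of 2.391. At day 2 it was 2 of 3 with 2.386, and at day 14 3 of 4 with 1.983. Camera called that list at no day (adjusted p = 0.196, 0.758 and 0.549). Over all 15 of these markers the mean levels in IP and input PBS libraries of PFC were 1.07 and 0.516, 0.642 and 0.409, and 0.704 and 0.409 at days 1, 2 and 14. In VCX they were 0.566 and 0.388, 0.321 and 0.33, and 0.331 and 0.352. Carry-over of input RNA at the rate of the neuron markers cannot account for the rise of the neutrophil and monocyte markers that entered this test. Their rise in the IP was 91.2 times what the neuron markers allow (quartiles 53.4 and 124 over 23 values). For microglia and macrophage markers the same value was 3.07 (quartiles 1.81 and 5.22 over 42 values), which leaves carry-over open. Only markers called up in both fractions entered, 5 to 7 neutrophil and monocyte markers per comparison, and the same genes recur among the values. The values bear only on carry-over at the rate of the neuron markers. Uptake of myeloid RNA as a single share cannot be told apart from other sources either, since the SD of the log2 IP to input ratio over markers was 0.875 for microglia and 0.534 for neutrophil markers, the latter over 3 markers. The share of the input rise seen in the IP ran from 41.7% for Csf3r to 1320% for Chil3 in PFC at day 2 and from 86.6% to 1160% in VCX at day 1, which goes against a single share, but few markers bear on it. Transcription of these genes by astrocytes after LPS, which the treatment groups allow, may contribute but was not tested, and 3 of the microglia markers (C1qa, C1qb and C1qc) also stand in the complement list.

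No gene passed at day 14, although 2800 and 2861 did in the IP at day 1. In the IP the median standard error at day 14 was 0.963 of that at day 1, in the area where it was higher. This excludes a wider spread between libraries for the median gene, not for every gene. The SD of the neuron marker level within IP groups was 0.449 to 0.587 at day 14 and 0.069 to 0.193 at day 1. A wider spread of some genes in the IP thus stays open. For the input the ratio of the median standard errors was 1.202, between the bounds set for the test, so a wider spread cannot be told apart there from other explanations. Effects of day 1 size hidden by low depth are excluded in both fractions for most genes that changed at least 2-fold at day 1. Those genes were selected on their day 1 estimates, whose own error was not counted, so the shares that follow may be too low. Of genes that changed at least 2-fold at day 1, 3.18% had a day 14 interval that reaches the day 1 effect in the IP, 14 of 423 in PFC and 13 of 427 in VCX, and 2.95% in the input, 10 of 353 and 11 of 359. Intervals reached 50% of the day 1 effect for 26.5% of those genes in PFC and 23.9% in VCX in the IP, and 30.3% and 27.9% in the input, so smaller lasting effects stay open. The LPS effect in the IP differed between day 1 and day 14 in 3453 genes, but a decline with time since injection cannot be told apart from the sequencing project, since the IP and input libraries of each day have their own.

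The LPS effect differed between IP and input in 2316 genes at day 1 and 550 at day 2, tested as a difference of effects. Between days it differed in 2614 genes for day 1 against day 2 and in 3453 for day 1 against day 14.

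Single libraries stood apart from the other 3 of their group in 16 of 299 tests by the gap between the extreme library and its neighbour relative to the range of the group, where chance gives about 1 in 20, or 14.9. The gap ratio was 0.846 for oligodendrocyte precursor markers in day 1 PFC whole tissue PBS replicate 3 (4.576 against 4.453 to 4.472). It was 0.857 for oligodendrocyte markers in day 1 VCX IP PBS replicate 4 and 0.855 for choroid plexus markers in day 1 PFC input PBS replicate 3. Endothelial markers gave 0.876 in day 1 PFC input LPS replicate 1, where the level was lowest. Microglia and macrophage markers gave 0.947 in day 1 VCX input PBS replicate 4 and 0.9 in day 1 VCX input LPS replicate 2. Total reads gave 0.878 in day 2 VCX IP PBS replicate 3, with 20.68 M against 44.63 to 47.95 M. Astrocyte markers gave 0.889 in day 2 PFC input PBS replicate 2 and red blood cell markers 0.911 in day 2 PFC input LPS replicate 1. Neuron markers gave 0.929 in day 2 VCX input PBS replicate 4, 0.92 in day 14 PFC input PBS replicate 2, and 0.86 in day 14 VCX IP LPS replicate 4 (5.44 against 4.166 to 4.344). At day 14 endothelial markers gave 0.853 in PFC IP PBS replicate 2 and 0.867 in PFC input LPS replicate 3. Neutrophil and monocyte markers gave 0.839 in day 14 PFC IP LPS replicate 1 and oligodendrocyte markers 0.881 in day 14 VCX input PBS replicate 3.

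For LPS against PBS at day 1, chance is an unlikely account of each comparison, since only the real split of 35 reached its count. A share of 1 in 35 is the lowest these splits can give, and it was not adjusted over the comparisons. The real and highest other counts were 2800 and 1 in the PFC IP, 2861 and 902 in the VCX IP, 2409 and 1 in the PFC input and 2470 and 1 in the VCX input. Chance is also an unlikely account at day 2, again with 1 split of 35. The counts there were 1069 and 1, 975 and 1, 557 and 1, and 313 and 27 in the same order. At day 14 the real count was 0 in all 4 comparisons, which all 35 splits reach whatever the values, so the splits say nothing there, and the highest others were 1, 292, 1 and 1. In whole tissue 7 of 35 splits reached the single gene called, so chance cannot be excluded there. Its highest other split called 1310 genes and set PBS replicates 1, 2 and 4 against the rest, which points to a structure of the samples other than the labels. The 902 genes in the VCX IP at day 1 came with PBS replicates 1 to 3 and LPS replicate 1 against the rest, and the 292 in the VCX IP at day 14 with PBS replicates 1 and 2 and LPS replicates 2 and 4, which likewise points to structure beyond the treatment. In the latter, PBS replicates 1 and 2 and LPS replicate 4 had neuron marker levels of 5.033, 5.353 and 5.44. LPS replicate 2 stood at 4.321 and the libraries set against them at 4.166 to 4.344.

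Between PFC and VCX, chance is an unlikely account for the input at day 1 (1987 against 2), the IP at day 2 (1033 against 2) and the input at day 2 (2392 against 1), each with 1 of 35 splits. The splits do not exclude it for the IP at day 1 (1027 against 1810), the IP at day 14 (624 against 874) and the input at day 14 (1167 against 1720), each with 2 of 35 splits as large. The genes called in the IP at day 1 were nevertheless shared with other days, which hold separate libraries. Day 2 shared 318 of those higher in PFC (23.8 expected) and 246 of those lower (16.4 expected), and day 14 shared 225 (15.6 expected) and 173 (9.16 expected), which argues against chance as the whole of the IP difference. In the input the layer 4 markers, a list fixed in advance, were lower in PFC in 9 of 9 cases at days 1, 2 and 14 (adjusted p = 0.0133, 0.00948 and 0.0031 with an estimated correlation), which argues against chance as the whole of the day 14 input difference. The split with 1810 genes exchanged PFC replicate 4 and VCX replicate 4, and without the latter the day 1 IP count was 2509. The day 14 IP split with 874 genes grouped PFC replicates 1 and 3 with VCX replicates 1 and 2. Their neuron marker levels were 5.103, 4.877, 5.033 and 5.353, against 4.148, 4.331, 4.207 and 4.326 in the rest. These higher splits point to a structure of the samples beside the area, which in the day 14 IP goes with the neuron marker level. For IP against input 1 of 100 splits was as large at each day, which makes chance an unlikely account, with 12706 against 11259, 12631 against 11186 and 12586 against 10929. The median of the other splits was 0 genes at each day. For the differences of LPS effects between areas the real count was 0, which all 100 splits reach whatever the values, so they say nothing, and the highest others were 1073, 108 and 1117. For the differences between IP and input, 1 of 100 splits was as large at day 1 (2316 against 562). At day 2 it was 2 of 100 (550 against 1589, a higher split that points to a structure of the samples). These splits exchanged only LPS and PBS labels within each day, area and fraction. An LPS effect alone can set the real split apart, so they do not exclude chance for a difference of effects. At day 14 the real count of 0 is reached by all 100 splits and says nothing, with 2546 as the highest other. Between days the splits have the same limit, with 1 of 100 as large for day 1 against 2 (2614 against 2259) and for day 1 against 14 (3453 against 2593).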

How the results depend on the processing

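Chosen after the data were seen were limma-voom, no rescaling, a pseudocount of 1, the neuron marker covariate and the fits without the 3 libraries under 10 M reads, and the other settings were planned. Of 216 alternatives other than leaving out single libraries, 206 gave a count within 1.5 times that reported and 10 did not. All 30 counts under a pseudocount of 1, all 29 without the sex covariate and all 5 without the 3 low-depth libraries stayed within that range, as did 29 of 30 with RLE factors, without rescaling, without the filter and with limma-voom. Fitting only the groups compared changed 5 of 18 counts, and it leaves fewer libraries to estimate the spread. These were 1832 for LPS in the VCX IP at day 1, 699 and 441 in the PFC and VCX IP at day 2, 115 in the VCX input at day 2, and 1434 for PFC against VCX in the input at day 2. The single gene of whole tissue became 4 with RLE factors, 3 without the filter, 4 without rescaling and 250 with limma-voom (164 up and 86 down). PFC against VCX in the IP at day 14 became 1327 with the neuron marker covariate. Camera called 406 lists in all comparisons, fry 396, and camera with an estimated correlation 109. The cause of the changes in whole tissue, with the covariate and in camera was not tested.

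Leaving out 1 library at a time gave 0 to 1432 genes in whole tissue, the latter without PBS replicate 3 and 0 without any of the other 6. For LPS the range was 640 to 1028 in the PFC IP at day 2 (lowest without LPS replicate 1) and 578 to 907 in the VCX IP at day 2 (578 without PBS replicate 3, 631 without LPS replicate 1). It was 158 to 317 in the VCX input at day 2 (158 without LPS replicate 2) and 0 to 1 in the VCX input at day 14 (1 without PBS or without LPS replicate 3). PFC against VCX ranged from 680 (without PFC PBS replicate 1) to 2509 (without VCX PBS replicate 4) in the IP at day 1, and from 667 (without PFC PBS replicate 4) to 871 in the IP at day 2.

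Without rescaling, IP against input split into 3736 higher and 9240 lower at day 1, 3635 and 9382 at day 2 and 3754 and 9205 at day 14, where rescaled values gave 6285 and 6421, 6218 and 6413, and 6552 and 6034. The PFC input at day 1 gave 1543 and 815 (1310 and 1099 rescaled) and the PFC IP at day 2 gave 644 and 537 (696 and 373 rescaled). The labels allowed no paired analysis. Each number in the titles occurs in 1 library within a project and ties no IP to an input and no PFC to a VCX library. At day 1 the highest scaled Cxcl10 of the LPS libraries was in a male in each set. It was 52.1 and 39.87 FPKM in the PFC and VCX IP, and 8.075 and 8.101 in the PFC and VCX input. These libraries may share an animal, and the tests between areas and fractions took no account of it. The planned DESeq2 alternative was dropped when the files were found to hold FPKM, although the recovered reads would have allowed a count test. Depth was lowest in the day 14 input, where 3 libraries had under 10 M reads.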

Other observations

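The gene lists and marker tests below were planned, while limma was chosen after the unit of the files was seen, and no hypothesis was tested on them. Genes of the vasculature and its barrier moved both ways in the astrocyte IP after LPS. Cldn5, a tight junction gene of brain endothelium, rose by 0.93 ± 0.25 in PFC and 1.18 ± 0.25 in VCX at day 1, and by 1.2 ± 0.20 and 1.18 ± 0.19 at day 2. The mean level of the endothelial markers, Cldn5 among them, was also higher in LPS libraries, by 0.153 in PFC and 0.443 in VCX at day 1 and by 0.461 and 0.516 at day 2 (exact permutation p = 0.257, 0.0286, 0.0571 and 0.0571, adjusted p = 0.557, 0.159, 0.235 and 0.235). Vegfa, the vascular endothelial growth factor gene, stood at -0.84 ± 0.13 and -0.88 ± 0.13 at day 1, Apln at -1.17 ± 0.13 and -1.33 ± 0.13, and Angptl4 at 1.01 ± 0.089 and 1.26 ± 0.089. In the list of blood-brain barrier and vascular growth genes 4 of 15 tested members rose, 4 fell and 7 did not pass, with 6 and 4 adjusted over the list alone in the PFC IP at day 1, and camera did not call it (camera adjusted p = 0.819). Genes that act on synapses or the matrix around them also split. Tnc and Ncan, both components of perineuronal matrix, were at -1.33 and -0.88 in the PFC IP at day 1, while Sparc rose by 1.12 ± 0.12 and the thrombospondin gene Thbs4 by 0.90 ± 0.27. Of that list 3 of 18 tested members rose, 6 fell and 9 did not pass, with 4 and 8 adjusted over the list alone (camera adjusted p = 0.0508). In the list of extracellular matrix and remodelling 4 of 18 tested members rose, 4 fell and 10 did not pass, with 5 and 5 adjusted over the list alone, with Timp4 at 1.04 and Col4a1 at 0.59 (camera adjusted p = 0.835).

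Single genes of metabolism also changed in the IP after LPS. The lipid synthesis genes Fasn and Fads2 were at -0.70 and -0.69 in PFC at day 1. Of fatty acid oxidation and synthesis 4 of 20 tested members rose, 8 fell and 8 did not pass, with 6 and 9 adjusted over the list alone (camera adjusted p = 0.796). The lactate transporter gene Slc16a3 rose by 1.4 ± 0.29 and 1.75 ± 0.29 at day 1 and by 1.97 ± 0.33 and 2.32 ± 0.31 at day 2, and the hexokinase gene Hk2 by 0.66 ± 0.15 and 0.82 ± 0.15 at day 1. For glycolysis, glycogen and lactate 4 of 24 tested members rose, 2 fell and 18 did not pass, with 4 and 2 adjusted over the list alone in the PFC IP at day 1 (camera adjusted p = 0.832). Among circadian clock genes Ciart and Dbp, both outputs of the clock, were at -0.64 and -0.58 in PFC and -0.81 and -0.83 in VCX at day 1, and Npas2 at 0.51 and 0.63. In that list 2 of 15 tested members rose, 4 fell and 9 did not pass, with 3 and 4 adjusted over the list alone in PFC (camera adjusted p = 0.802). Among receptor genes that fell at day 1 were the endothelin receptor gene Ednrb at -0.79 and -0.99, the adrenergic receptor gene Adra1a at -0.66 and -0.48 and the glutamate receptor gene Grm3 at -0.49 and -0.44. Over the G protein-coupled receptor and calcium signalling list 2 of 24 tested members rose, 5 fell and 17 did not pass, with 2 and 5 adjusted over the list alone (camera adjusted p = 0.188). Tdo2, which degrades tryptophan, rose by 1.00 ± 0.30 and 1.34 ± 0.30 and Maob by 0.44 ± 0.076 and 0.43 ± 0.076, in a list where 2 of 5 tested members rose, 1 fell and 2 did not pass, with 2 and 1 adjusted over the list alone (camera adjusted p = 0.234). Layer-varying astrocyte genes had 3 of 11 up and 1 down, 3 and 1 adjusted over the list alone, Thbs4 and the angiotensinogen gene Agt at 0.90 and 0.55 among those up (camera adjusted p = 0.464).

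Levels of the cell type markers are given as mean log2 of CPM plus 1. Astrocyte markers ran from 10.69 to 10.98 in the IP and 7.13 to 7.56 in the input, and neuron markers from 4.1 to 5.44 and 8.27 to 8.68. Red blood cell markers were at 0.74 to 1.3 in the IP and 0.27 to 0.56 in the input, and choroid plexus markers at 0.5 to 1.81 and 0.51 to 1.02. Lymphocyte markers stood near the floor, at 0.01 to 0.27 in the IP, and were higher in LPS than in PBS libraries at day 2 by 0.135 in the PFC IP and 0.119 in the VCX IP (exact permutation p = 0.0286 and adjusted p = 0.159 each). The same markers were higher by 0.091 in the PFC IP at day 14, with the same p-values by the exact permutation test. Choroid plexus markers were higher by 0.261 in the VCX IP at day 1 (exact permutation p = 0.0286, adjusted p = 0.159) and lower by 0.276 in the PFC IP (exact permutation p = 0.4, adjusted p = 0.686), where PBS replicate 2 stood at 1.814 and the other PBS libraries at 0.788, 1.274 and 0.858. Oligodendrocyte precursor markers in the PFC IP at day 1 had 1 of 7 up and 0 down, 0 and 0 adjusted over the list alone (camera adjusted p = 0.819).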
